A study of Mus musculus with 2 samples.

How the data were processed

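RNA was sequenced from CD45-negative, Sftpc-positive lung cells sorted from mice of a tumour-bearing and of a normal group, with 1 library per group. How Sftpc was detected in the sort is not given in the sources used here. Per the labels' protocols, RNA was treated with DNase, selected with oligo(dT) beads, fragmented, primed with random hexamers and amplified by PCR. The strand setting, the aligner, the counting tool and the gene annotation are not given in the sources used here. Per the submitters' processing notes, Trimmomatic and the mm10 build were used, without versions. The authors deposited 1 table per library with the GeneID, symbol, description and RPKM (reads scaled to gene length and library total) of each gene, per the file headers. No other unit was in these tables, and whether animals were pooled within a library is not given in the sources used here.

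RPKM divides by gene length and by the library total, so a few very abundant genes lower the values of the rest. Sftpc alone made up 18.6% of the sum of RPKM in the control library and 11.2% in the tumour-bearing library. Values were compared as deposited, without further scaling. A gene missing from a table was taken as 0. Because oligo(dT) selection was combined with PCR and no molecular identifiers are described, reads are not independent molecules, and intervals cover counting error only.

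The RPKM values kept enough digits to recover whole read numbers. For genes with few reads, the ratio of the 2 libraries' values was a ratio of small whole numbers times 1 constant, the ratio of the library totals (0.990). The totals themselves, 5335352 and 5387114 reads, were those at which the most implied gene lengths matched GENCODE M21 transcript lengths. Rows were in descending order of reads, which settled the remaining multiples. Reads were recovered for 15096 of 15113 genes (99.9%), and the implied length was whole within 0.02 base for 99.97% of these. The length equalled that of a GENCODE M21 transcript of the same symbol for 12.0% of them. Of 28181 neighbouring row pairs, 4 were out of order. The order was itself used in the recovery, and whole lengths were required for the most-read genes, so neither is a fully independent check. The recovered reads summed to 91.3% and 94.5% of the totals without Sftpc, whose own multiple was not settled, so Sftpc has no read number and no interval. The totals are estimates of this work and not values stated by the authors. The recovered reads were used for counting intervals and as an added alternative, and the deposited RPKM for the main values.

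The main measure was log2((tumour-bearing RPKM + 1)/(control RPKM + 1)) for 12288 genes at 1 RPKM or more in at least 1 library. This scale understates the ratio of low genes, so folds in the text are direct ratios of RPKM, with exact (Clopper-Pearson) conditional binomial 95% intervals of the ratio of the reads. A gene with 0 reads in 1 library was given a lower bound against a floor of 3 reads. With 1 library per group no test of the conditions was possible, and a size rule of 2-fold was used. For each list with 5 or more tested genes, the median log2 ratio was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins. The range from 2.5 to 97.5 was taken as inside, which describes these 2 libraries only. The interval of a list's median is the 95% order-statistic interval over its genes, and the whole range for lists of 5.

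Grouping, gene lists, size rule and alternatives were fixed before the data were examined. The genes named were Sftpc and Ptprc, the 12 genes with the highest and the 12 with the lowest log2 ratio among those at 10 RPKM or more in the higher library, and up to 4 members per list with the largest absolute log2 ratio at 5 RPKM or more. The AT2, pan-leukocyte, neutrophil and sex-linked lists could be named in full, and ribosomal, mitochondrial, unnamed and immune receptor segment genes were left out of the ranking. Current symbols and coordinates were taken from a RefSeq table of the GRCm38 assembly, the assembly mm10 denotes, by GeneID for 15080 of 15113 genes. Of the symbols in the tables, 1039 were older names, including 10 turned into dates by spreadsheet software.

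Alternatives were trimmed-mean scaling, upper-quartile scaling, pseudocounts of 0.1 and 5, no low-value filter, a filter at 5 RPKM, centring on the median, removal of the marker genes of other cell types, thresholds of 1.5-fold and 4-fold, and random lists unmatched or matched in 10 bins. Recovered reads scaled to the library total with 0.5 added, the counting interval wholly past 2-fold, and medians with genes at 0 reads at their bound were added after the data were examined.

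The procedure was tested on simulated data, with Poisson reads for 15096 genes at the mean levels of the 2 libraries and 200 genes given known folds. Reads were recovered for 99.99% of simulated genes, and 99.9% of those were correct. The 2-fold rule found 98.0% of 50 genes made 4-fold higher, 89.6% of 48 made 4-fold lower, 90.0% of 50 made 3-fold higher and 70.2% of 47 made 3-fold lower. Of 11720 genes left equal, 40 (0.341%) passed it by counting noise alone, and 3 of 100 random lists of 15 equal genes lay outside the range. This simulation holds no variation between animals. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.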

Results

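Gene expression was measured by RNA sequencing in 2 libraries of mouse lung epithelial cells, 1 from a tumour-bearing group and 1 from a normal wild-type group. The number of mice behind each library is not given in the sources used here. The tumour-bearing group came from a model of spontaneous lung metastasis, in which 1000000 luciferase-labelled LLC cells (Lewis lung carcinoma, a mouse lung cancer line) are placed under the skin of the back. The animals were C57BL/6 mice aged 6 to 8 weeks. Lung was dissociated, and cells negative for CD45, the leukocyte surface protein encoded by Ptprc, and positive for Sftpc, surfactant protein C of alveolar type 2 (AT2) cells, were sorted. The deposited RPKM values corresponded to totals of 5335352 reads in the control library and 5387114 reads in the tumour-bearing library. The control library had 13932 genes with at least 1 read and the tumour-bearing library 14283, with 13102 in both. Each group held 1 library, so no difference below has a replicate check, and no p-value is given. Intervals beside folds are exact 95% intervals from the read numbers and cover counting error only.

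Of the 2 genes of the sort gate, Sftpc was high and Ptprc low in both libraries. Lists of other cell types were read as well. Summed RPKM in the control and tumour-bearing library was 160589 and 109559 for AT2 genes and 38820.5 and 43001.1 for club secretory genes. It was 2642 and 4093 for AT1 genes and 585 and 1708 for fibroblast genes. The gate genes thus do not show that either library came from AT2 cells alone. Sftpc (GeneID 20389, chromosome 14, 70520941 to 70524081 on mm10) was the most abundant gene, at 94902 RPKM in the control library and 54968 RPKM in the tumour-bearing library, a log2 ratio of -0.79. Ptprc (GeneID 19264, chromosome 1, 138062859 to 138175756) had 12 reads in the control library and 2 in the tumour-bearing library. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were read in both libraries, at 9.94, 14.9, 5.72 and 3.37 RPKM in the control and 11.5, 21.1, 2.92 and 3.73 RPKM in the tumour-bearing library. Xist, the X-inactivation RNA of female cells, had 36 reads in the control library and 9 in the tumour-bearing library.

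The comparison of the 2 libraries addressed how lung epithelial cells differ in tumour-bearing mice, the setting that the series title calls the pre-metastatic niche. Median log2 ratios were above 0, meaning higher in the tumour-bearing library, for acute-phase genes, AT1 genes, fibroblast markers and endothelial markers. They were below 0 for immediate early, cholesterol synthesis, MHC class II and AT2 genes. Of 12288 genes at 1 RPKM or more in at least 1 library, 1153 (9.38%) were at least 2-fold higher and 802 (6.53%) at least 2-fold lower in the tumour-bearing library on the log2(RPKM + 1) scale, and 10333 lay within 2-fold. With a pseudocount of 5 these numbers were 370 and 190, so they depended on how low values were treated. Of 43 gene lists fixed before the data were examined, 39 had 5 or more tested genes, and the median log2 ratio of 21 lay outside the central 95% of random lists matched on expression, 14 above and 7 below, against 1.95 expected if lists were drawn at random. Some lists share genes, and genes of a list can vary together. The number 1.95 is therefore not what 2 libraries of the same condition would give, which was not measured. Among those outside, the interval of the median over genes included 0 for the alveolar transitional, smooth muscle and pericyte, complement, MHC class II, fatty acid and phospholipid synthesis, fatty acid oxidation and unfolded protein response lists.

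**Figure D1:**
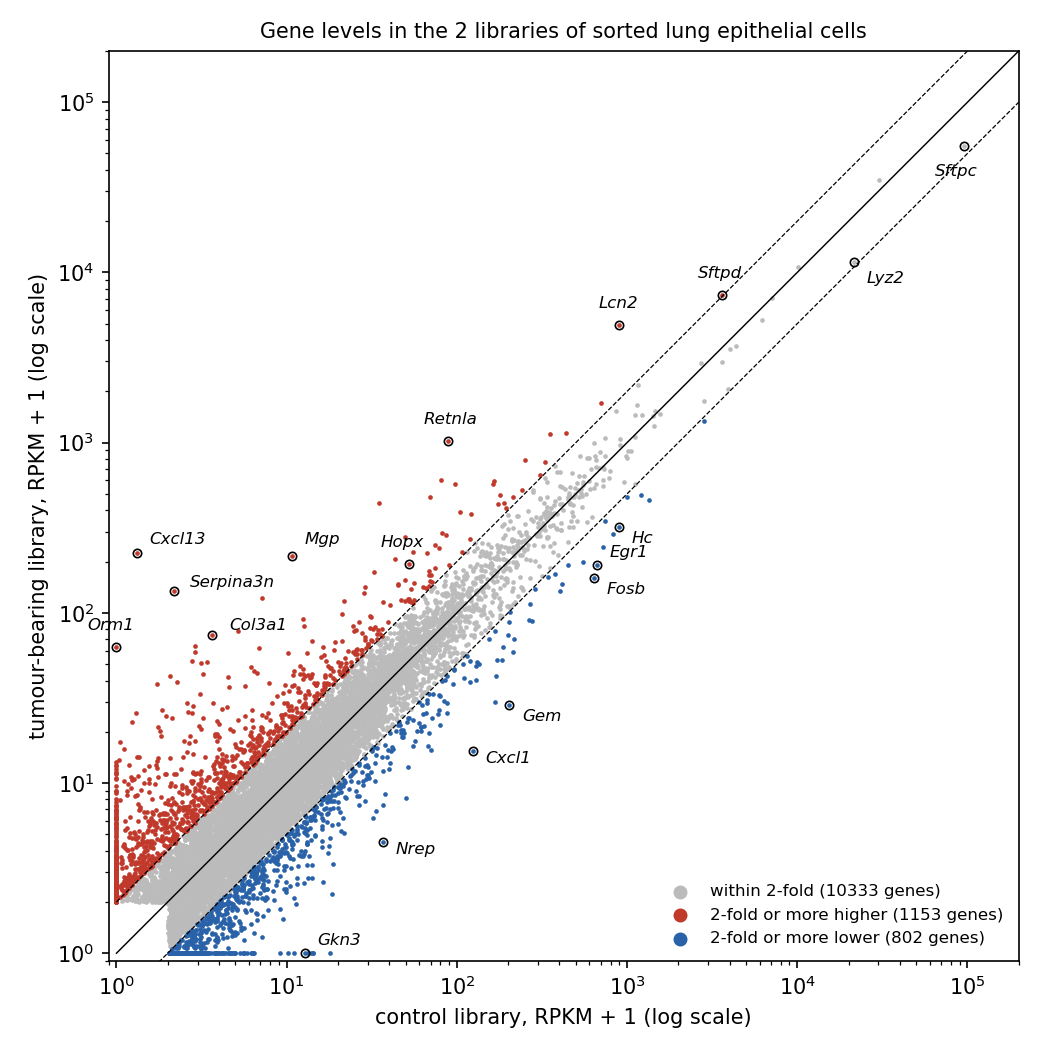
Each point is 1 of 12288 genes, with its RPKM + 1 in the control library on the horizontal axis and in the tumour-bearing library on the vertical axis, both on log scales. The solid line marks equal values and the dashed lines 2-fold; 1153 genes lie above the upper dashed line and 802 below the lower one, and 18 genes are circled and named.

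The gene with the highest log2 ratio among those at 10 RPKM or more was Cxcl13 (GeneID 55985, chromosome 5, 95956939 to 95961068), a chemokine that attracts B cells, at 0.323 RPKM in the control and 225 RPKM in the tumour-bearing library. This was a 698-fold difference with an interval of 193 to 5767, from 2 and 1409 reads. Orm1 (GeneID 18405, chromosome 4, 63344556 to 63348163), an acute-phase plasma protein, had 0 reads in the control and 258 in the tumour-bearing library, at least 85.2-fold higher against a floor of 3 reads. Serpina3n (GeneID 20716), a serine protease inhibitor, was 114-fold higher (66.7 to 215), and Fkbp5 (GeneID 14229), a co-chaperone of steroid receptors, was 51-fold higher (30.8 to 91.6). The other 8 of the 12 highest were Igfbp4, Sphk1, Col1a2, Col3a1, Mgp, Cpxm1, Saa3 and Gpihbp1, with log2 ratios between 4.22 and 4.45. Among them, Col1a2, Col3a1 and Mgp belong to the fibroblast list, so a place in this ranking does not assign a gene to epithelial cells.

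At the other end, Gkn3 (GeneID 68888, chromosome 6, 87383319 to 87388935) had 50 reads in the control and 0 in the tumour-bearing library, at least 16.8-fold lower. Cxcl1 (GeneID 14825), a neutrophil-attracting chemokine, was at 123 RPKM in the control and 14.4 RPKM in the tumour-bearing library, 8.51-fold lower (6.69 to 11). Csf2 (GeneID 12981), which encodes the growth factor GM-CSF, was 5.99-fold lower (4.02 to 9.21), Gem, a small GTPase gene, 7.26-fold lower (6.48 to 8.16), and Egr2, an immediate early transcription factor gene, 9.48-fold lower (6.31 to 14.8). The remaining genes of this group were Smim26, Nrep, Tinag, Pgc, Acoxl, Tmem178 and Cox20, with log2 ratios from -3.07 to -2.31.

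Among the epithelial lists, AT2 identity genes had a median below 0 and AT1 identity genes, those of the thin gas-exchange cell, a median above 0. The AT2 median was -0.38 over 23 genes, with 4 genes at least 2-fold lower, 2 at least 2-fold higher and 17 within 2-fold. Hc, complement component C5, was at 900 RPKM in the control and 320 RPKM in the tumour-bearing library, 2.81-fold lower (2.74 to 2.88), and Etv5, a transcription factor gene of AT2 cells, was 2.11-fold lower (2.02 to 2.2). The lysozyme genes Lyz1 and Lyz2, near-identical copies whose reads can be exchanged, were 2.1-fold and 1.89-fold lower. The surfactant genes moved apart: Sftpd was 2.04-fold higher (2.01 to 2.07), from 3633 to 7410 RPKM, while Sftpa1 and Sftpb had log2 ratios of 0.00 and 0.08. Of 18 AT1 genes, 17 had a log2 ratio above 0 and 10 were at least 2-fold higher, with a median of 1.05. Fibroblast and endothelial markers were also higher in this library, with medians of 2.56 and 1.60. Whether a different mix of cells lay behind the AT1 values was not tested. Spock2 was 7.08-fold higher (6.19 to 8.12), Pdpn, encoding podoplanin, 4.82-fold (4.12 to 5.66), Scnn1g, a sodium channel subunit gene, 4-fold (3.47 to 4.62), and Hopx, an AT1 transcriptional cofactor gene, 3.74-fold (3.32 to 4.22).

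Genes of the alveolar transitional state had a median of 0.34 over 18 genes, 15 of them within 2-fold, at percentile 97.8, a call lost under 5 of 11 alternatives. Krt7 was 3.77-fold higher in the tumour-bearing library and Areg 3.69-fold lower. The club secretory, ciliated, basal and neuroendocrine lists lay inside the range of random lists, with medians of -0.23, -0.07, -0.15 and 1.04 over 11, 16, 6 and 5 genes. The neuroendocrine median was 3.01 and its percentile 99.7 with a pseudocount of 0.1, and the percentile was 99.5 against random lists not matched on expression. Its median was 1.85 on recovered reads, 0.28 with a pseudocount of 5 and 0.47 with no filter, at percentiles 93.2, 91.3 and 94.6. In the club secretory list Retnla was 11.6-fold higher (10.3 to 13.2), from 87.8 to 1019 RPKM, and Cyp2f2 was 2.45-fold lower (2.37 to 2.53).

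Acute-phase and antimicrobial genes were higher in the tumour-bearing library. The median log2 ratio was 1.66 over 14 genes, 9 of them at least 2-fold higher and 0 at least 2-fold lower. On the ratio of reads, with Orm1 at its bound, the median was 1.69. Besides Orm1 and Serpina3n, Saa3, a serum amyloid A gene, was 29.1-fold higher (12.2 to 91), and Cfb, complement factor B, 29.3-fold higher (12.3 to 91.6). Saa and Orm genes have close paralogs that can share reads. Lcn2, lipocalin 2, singled out after its values were seen, was the most abundant member, at 901 RPKM in the control and 4899 RPKM in the tumour-bearing library. The complement list had a median of 0.88 over 11 genes, with 5 at least 2-fold higher and 2 at least 2-fold lower. Its most abundant member, Hc, also an AT2 gene, was among the lower ones. The summed RPKM of the list was 1115 in the control and 662 in the tumour-bearing library, opposite to the median. This median was 0.55 with a pseudocount of 5, 0.56 with no low-value filter and 1.87 with a filter at 5 RPKM. Serping1 and C4b were 10-fold and 8.77-fold higher, alongside fibroblast markers that were also higher in this library.

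Markers of other lung cell types differed between the libraries. The fibroblast list had a median of 2.56 over 12 genes, 9 of them at least 2-fold higher. On the ratio of reads, with nothing added and the gene at 0 reads at its bound, the median was 3.52. The median was 4.26 with a pseudocount of 0.1 and 1.67 with 5. The collagen genes Col1a1, Col1a2 and Col3a1 were 30.2-fold (21.3 to 44.4), 39.5-fold (27.4 to 59.3) and 27.6-fold (22.1 to 35) higher, reaching 38.5, 41.8 and 73.5 RPKM, and Mgp, matrix Gla protein, was 21.9-fold higher, at 214 RPKM. Folds within the list were unequal. Dcn and Col6a1, named after their values were seen, were 4.45-fold (3.58 to 5.58) and 3.13-fold (3 to 3.28) higher, at 44.7 and 379 RPKM in the tumour-bearing library. The endothelial list had a median of 1.60 over 14 genes, 12 of them above 0 and 11 at least 2-fold higher. Cldn5 was 24.3-fold higher (10.9 to 67.2), Vwf 26.7-fold (15.4 to 50.6), Lyve1 15.2-fold (10.1 to 23.8) and Eng 6.58-fold (4.92 to 8.95), at 19.2, 7.35, 27.3 and 18.3 RPKM in the tumour-bearing library. The receptor genes Kdr and Tek, named after their values were seen, were the members below 0, with Kdr 1.89-fold lower (1.47 to 2.43) and Tek at a log2 ratio of -0.18. Macrophage and monocyte genes had a median of 1.37 over 10 genes, with 6 at least 2-fold higher and 1 at least 2-fold lower. The median was 1.44 on the ratio of reads with the 3 genes at 0 reads at their bound. It was 0.58 with no low-value filter. Cd68 was at 7.81 and 31.5 RPKM, and C1qb had 0 and 32 reads. C1qa, named after its values were seen like Chil3, had 11 and 17 reads, and Chil3 had 19 and 0, at least 6.39-fold lower. The smooth muscle and pericyte median was 1.18 over 5 genes, 3 of them at least 2-fold higher, 0.51 with a pseudocount of 5 and 0.53 with no filter.

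Unlike the macrophage and monocyte list, the pan-leukocyte and neutrophil lists lay inside the range of random lists. The pan-leukocyte median was 0.00 over 7 tested genes and the neutrophil median -0.51 over 5. The neutrophil median was -0.23 with a pseudocount of 5, and with no low-value filter its sign was opposite, at 0.11. S100a9 had 5 reads in the control and 0 in the tumour-bearing library, while Ltf, lactoferrin, which epithelial cells also make, was 5.02-fold higher (4.51 to 5.6). The erythroid and platelet list had a median of 0.92 over 6 genes, at percentile 97.4, and lay outside the range in 7 of 9 alternatives. On the ratio of reads, with the gene at 0 reads at its bound, its median was 1.57. Its median was 1.74 with a pseudocount of 0.1 and 0.35 with 5. Its haemoglobin genes Hba-a1 and Hba-a2 are near-identical and had 3 and 16 reads in the control and 17 and 7 in the tumour-bearing library. The T and NK cell, B cell, mesothelial and sex-linked lists had fewer than 5 tested genes and were not ranked. The first held 1 tested gene, with a log2 ratio of -1.40, and the others had medians of -0.70, 1.91 and 0.15 over 2, 2 and 4 genes. With no low-value filter 3 of them could be ranked: the mesothelial list lay above the range of random lists, with a median of 0.98, and the T and NK cell and sex-linked lists inside it, with medians of -0.24 and 0.11.

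Pre-metastatic niche mediators, secreted and matrix genes tied in the field to tumour cell seeding, had a median of 1.54 over 18 genes. Of these, 12 were at least 2-fold higher and 3 at least 2-fold lower. On the ratio of reads, with the 4 genes at 0 reads at their bound, the median was 2.46. It was 2.37 with a pseudocount of 0.1, 0.57 with 5, 2.54 with a filter at 5 RPKM and 2.38 on recovered reads. Fn1, fibronectin, was 20.8-fold higher (17.2 to 25.5), Cxcl12, a chemokine made by stromal cells, 26.7-fold (17.7 to 42.5), and Timp1, a metalloproteinase inhibitor, at least 19.8-fold. The mesenchymal transition list had a median of 1.15 over 12 genes, 7 at least 2-fold higher. On the ratio of reads, with the gene at 0 reads at its bound, the median was 1.35. Vim was at 6.13 and 24.2 RPKM and Ccn2 was 5.2-fold higher (4.4 to 6.17). Both lists moved together with the fibroblast list, whose median was 2.56, and fibroblasts express many of their genes. The epithelial junction and polarity list was inside the range of random lists, with a median of 0.32 and all 15 genes within 2-fold.

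Immediate early genes, which respond within minutes to stimulation, were lower in the tumour-bearing library. The median was -0.95 over 19 genes, with 18 below 0, 9 of them at least 2-fold lower, and 0 at least 2-fold higher. Fosb was 3.97-fold lower (3.82 to 4.13), from 635 to 160 RPKM, Egr1 3.52-fold (3.38 to 3.66), Nr4a1 3.09-fold (2.87 to 3.33) and Atf3 3.03-fold (2.85 to 3.22). The unfolded protein response list had a median of -0.39 over 17 genes, 16 of them within 2-fold and 5 above 0. The exception was Ddit3, a stress-induced transcription factor gene, 4.7-fold lower (2.87 to 8.04), while Herpud1 was 1.77-fold higher (1.67 to 1.87). The heat shock list had a median of -0.27 over 13 genes, 11 of them within 2-fold, at percentile 1.3, and 5.67 against random lists not matched on expression. Of its members 11 were below 0 and 2 above 0, with Hsph1 2.33-fold lower and Hspb1 2.33-fold higher.

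Chemokines and cytokines were divided, with 8 of 26 genes at least 2-fold higher and 11 at least 2-fold lower. The median was -0.14, inside the range of random lists. It was -0.20 on the ratio of reads, with the 8 genes at 0 reads at their bound. It was -0.36 at percentile 0.27 with no filter and -0.55 at percentile 0.32 with a filter at 5 RPKM. Cxcl12 and Cxcl14, at 20.3 and 5.32 RPKM in the tumour-bearing library, were higher beside the fibroblast markers, and Cxcl1 and Csf2 were lower. The Toll-like receptor and NF-kB list had a median of -0.01 over 26 genes, with 3 at least 2-fold higher and 3 at least 2-fold lower. The NF-kB feedback genes Nfkbia, Nfkbiz and Tnfaip3 were 2.79-fold (2.62 to 2.98), 3.58-fold (3.2 to 4.02) and 2.44-fold (2.12 to 2.81) lower, beside immediate early genes that were also lower, and a difference in handling was not tested for them. Ly96, encoding a TLR4 co-receptor, was 3.11-fold higher (1.28 to 8.63), and the other two, Cd14 and Irak3, named after their values were seen, were 2.17-fold higher (1.93 to 2.44) and at least 5.94-fold higher, the latter from 0 and 18 reads. Interferon-stimulated genes had a median of -0.02, with 23 of 27 genes within 2-fold.

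The antigen presentation lists went in opposite directions. MHC class I genes had a median of 0.46 over 16 genes, 13 of them with a log2 ratio above 0 and 14 within 2-fold, and H2-D1 was 2.36-fold higher (2.26 to 2.47), although H2 genes are close copies whose reads can be exchanged. With a filter at 5 RPKM this list lay inside the range of random lists, at percentile 97.2. MHC class II genes had a median of -0.79. On the ratio of reads, with the 2 genes at 0 reads at their bound, it was -0.80 over the same 10 genes. Of these 4 were at least 2-fold lower, 5 within 2-fold and 1 at least 2-fold higher, H2-DMb2, named after its values were seen, with 0 and 6 reads. H2-Aa was at 743 and 343 RPKM, 2.17-fold lower (2.05 to 2.29), H2-Eb1 2.29-fold lower (2.1 to 2.49), and Ciita, the class II transactivator, 3.43-fold lower (2.66 to 4.47). Immune checkpoint ligands had a median of 0.09 over 8 genes.

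Cholesterol synthesis genes had a median below 0 and genes of energy metabolism medians above 0, with most members within 2-fold. All 19 tested cholesterol synthesis genes had a log2 ratio below 0, with a median of -0.74 and 5 at least 2-fold lower. Nsdhl, Msmo1 and Dhcr7, enzymes of sterol synthesis, were 2.65-fold (2.23 to 3.16), 2.53-fold (2.24 to 2.87) and 2.29-fold (1.83 to 2.9) lower. Fatty acid and phospholipid synthesis genes had a median of -0.21 over 21 genes and went both ways, with 9 above 0, 12 below 0 and 17 within 2-fold. Of these genes 4 were at least 2-fold lower, including the desaturase gene Fads2, 3.23-fold lower (2.57 to 4.09). This call was lost with no filter, with a filter at 5 RPKM and against random lists not matched on expression, at percentiles 3.76, 4.68 and 5.09, and the median was -0.12 and -0.11 in the first and second of these. Hypoxia and glycolysis genes had a median of 0.62, or 0.66 on the ratio of reads with the gene at 0 reads at its bound. Of 22 genes 17 lay within 2-fold. The other 5 were higher, with Hk2, hexokinase 2, 2.7-fold higher (2.39 to 3.06). The oxidative phosphorylation median was 0.41 over 33 genes, 29 of them with a log2 ratio above 0 and 29 within 2-fold. The fatty acid oxidation median was 0.40 over 17 genes, 5 of them below 0 and 15 within 2-fold, with Cpt2 2.37-fold higher (1.81 to 3.12).

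The remaining lists lay inside the range of random lists. Medians were -0.15 for proliferation over 15 genes, 0.09 for oxidative stress over 17, 0.38 for p53 targets over 13, -0.12 for the Wnt pathway over 17, 0.04 for the TGF-beta pathway over 19, and 0.08 for extracellular vesicle uptake and release over 15. The p53 list was at percentile 98.1 with no filter. Within them, Cat, encoding catalase, was 2.81-fold lower (2.69 to 2.94), Nqo1, an antioxidant enzyme gene, 3.19-fold higher (2.23 to 4.64), and Rab27b, a GTPase gene of vesicle release, 2.62-fold lower (2.26 to 3.03).

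**Figure D2:**
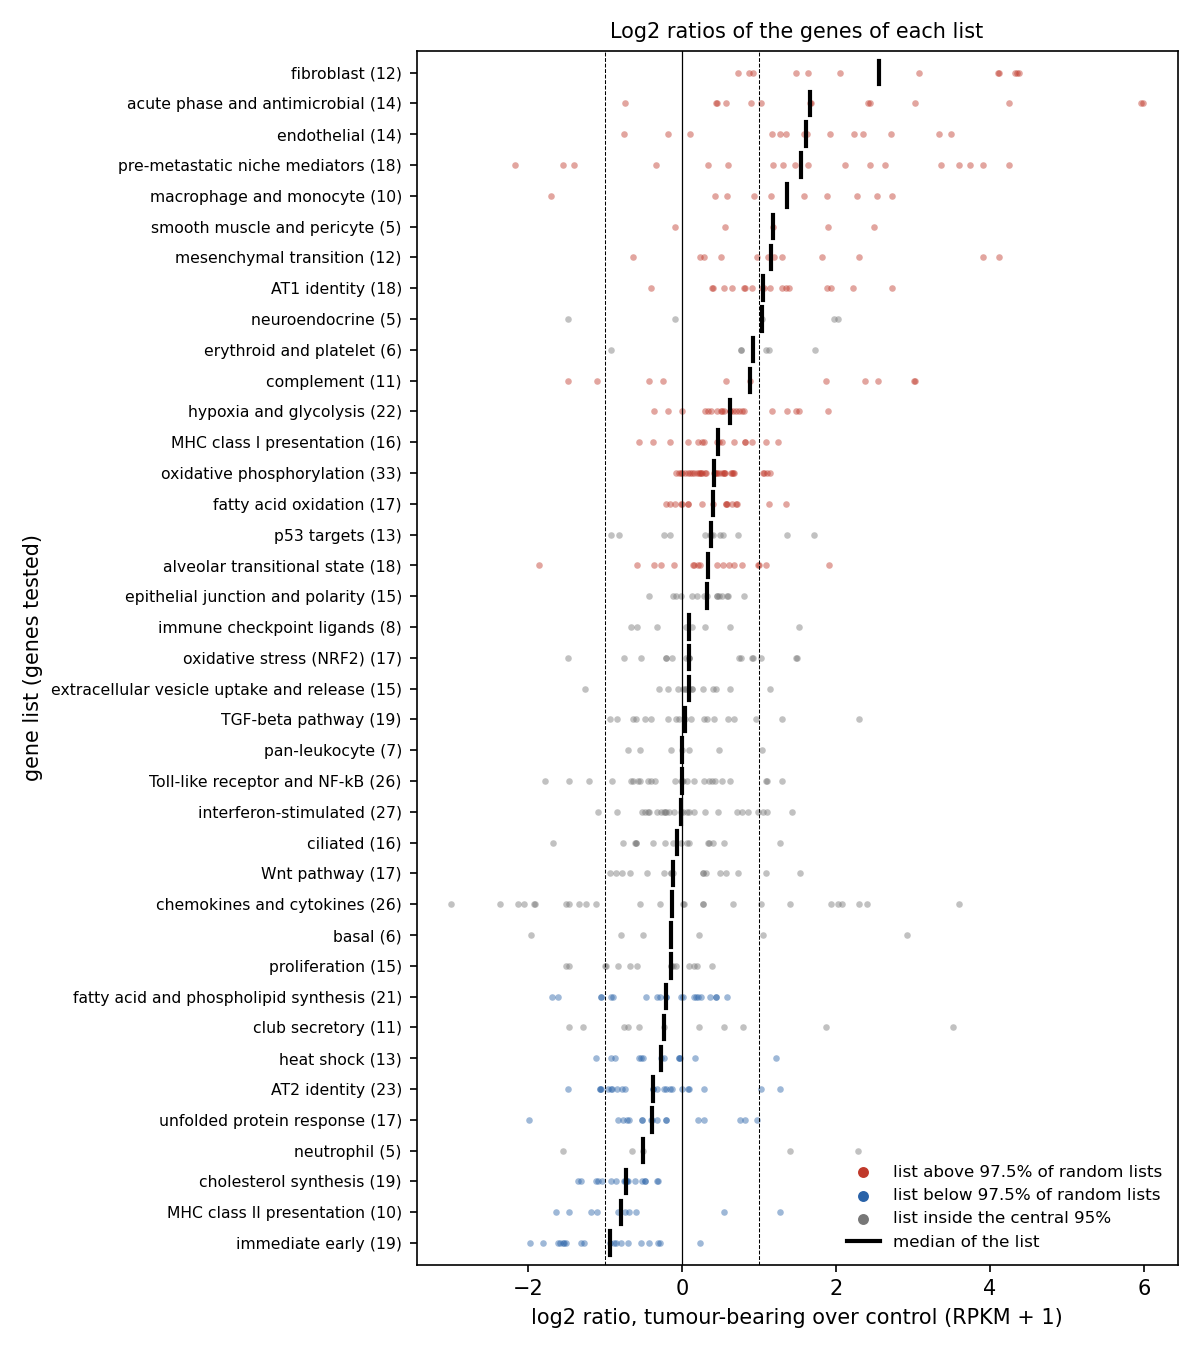
Each row is 1 of the 39 gene lists with 5 or more tested genes, each point is the log2 ratio of 1 gene (tumour-bearing over control, RPKM + 1), and the black bar is the list's median. Lists above the central 95% of random lists are red (14), those below are blue (7) and the others grey (18); medians run from -0.95 for immediate early genes to 2.56 for fibroblast genes.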

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

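Alternatives that used the recovered reads, the counting interval or the bound for genes at 0 reads were chosen after seeing the data; the others were planned. The number of lists outside the range of random lists, 21 as reported, was between 17 and 23 under the alternatives. The lowest number came with removal of the marker genes of other cell types. By construction this takes out the macrophage and monocyte, endothelial, fibroblast, and smooth muscle and pericyte lists. Of the 21 lists, 17 were outside in each alternative in which they could be ranked. The other 4 were the alveolar transitional, MHC class I, fatty acid and phospholipid synthesis, and heat shock lists. No list outside the range and no named gene at least 2-fold different changed direction. Among lists inside the range, some medians did change sign: the basal, neutrophil and Wnt lists with no filter, the interferon list with a filter at 5 RPKM, the pan-leukocyte list with either scaling, centring or no filter, the TGF-beta list with either scaling or centring, and the checkpoint, oxidative stress and vesicle lists with upper-quartile scaling. Of 377 recomputed list medians, 375 lay within the interval of the main median. Of 1644 recomputed log2 ratios of named genes, 1484 moved by no more than their counting error, or a small fixed margin where the counting interval was not finite. Settings that change only the filter leave a gene's ratio as it was, and scaling and centring shift genes nearly alike. The number 1484 is therefore no measure of how robust the genes are.

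The gene numbers depended on low values and on the threshold, with 1153 higher and 802 lower as reported. They were 370 and 190 with a pseudocount of 5, 687 and 419 with a filter at 5 RPKM, 2383 and 1978 at 1.5-fold, and 204 and 75 at 4-fold, since each of these settings by construction admits fewer or more genes. With a pseudocount of 0.1 the lower number was 1247, and with the counting interval wholly past 2-fold it was 458, beside 1539 and 771 higher. Upper-quartile scaling shifted log2 ratios by about -0.10 and gave 962 higher and 931 lower. Trimmed-mean scaling gave 1069 and 849.

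No paired analysis was possible because each group has 1 library. A comparison in another deposited unit was not run, since the tables hold RPKM alone. Depth limits genes with few reads. For S100a9, with 5 and 0 reads, a difference was hardly measurable, and Ptprc was 6.06-fold lower with an interval from 1.35 to 55.7, while the variation between animals was not measured at all.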

Other observations

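The lists and genes of the next paragraph were chosen after their values were seen, as were the tests on junction genes, neutrophil genes, glucocorticoid-induced genes, transcript length and GC content, and heat shock genes further on.

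Genes of alveolar fluid and ion transport had a median log2 ratio of 0.75 (interval -0.11 to 1.84) over 10 genes, with 4 at least 2-fold higher and 6 within 2-fold. Scnn1a and Scnn1b, subunits of the epithelial sodium channel, were at 164 and 20.2 RPKM in the control and at 590 and 67.5 RPKM in the tumour-bearing library, and the sodium pump subunit gene Atp1b1 was at 439 and 1136 RPKM. Aqp1, a water channel gene that endothelial cells also express, had 44 and 317 reads, beside endothelial markers that were also higher, and Aqp4 and Cftr had log2 ratios of -0.12 and -0.11. Cyp2b10, a cytochrome P450 gene, was at 79.6 and 606 RPKM. Pmvk, phosphomevalonate kinase, was at 33.8 and 438 RPKM, opposite to the 19 tested genes of the cholesterol synthesis list. Fgf23, a phosphate-regulating hormone gene, had 0 reads in the control and 149 in the tumour-bearing library, and Prg4, encoding lubricin, 0 and 266.

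Fibroblast and endothelial markers were higher in the tumour-bearing library although the sort was for Sftpc-positive cells, and how far it removed both types is unknown, since how Sftpc was detected is not given in the sources used here. Epithelial junction genes were not lost, with a median of 0.32, which argues against a loss of junction genes across the sorted cells as a whole. A loss in a small part of the cells would not show in this median. Trimmed-mean scaling left the fibroblast median at 2.52, but it shifted log2 ratios by only about -0.05 and so could not have moved this median far. The median over all tested genes was 0.06, which argues against 1 scaling factor for the whole library as the cause. A further list of 24 fibroblast genes was drawn up, none in another list and 7 of them at 1 RPKM or more in the control. Its median was 1.16 (interval 0.74 to 2.20) over 17 tested genes, past the log2 ratio of 1 set beforehand for fibroblast RNA. On the ratio of reads, with the 2 genes at 0 reads at their bound, the median was 1.92. Genes below 1 RPKM in both libraries are left out. All tested genes but the 7 at 1 RPKM or more in the control passed the filter only through the tumour-bearing library, so their log2 ratios had to be above 0. Of the 23 genes read, 10 were tested and at least 2-fold higher. The untested genes, below 1 RPKM in both libraries, cannot reach 2-fold on this scale. A median over all 23 would therefore lie below 1, short of the value set for fibroblast RNA. The list does not decide the question, and RNA from fibroblasts stays a candidate source. Of the 17 tested genes 15 were above 0, a number largely fixed by the filter. The others, Clec3b and Efemp1, both among the 7 free to go either way, had log2 ratios of -0.51 and -1.19. The abundant Col3a1 and Mgp of the first list reached 73.5 and 214 RPKM. Members of that list differed by unequal factors, with Col3a1 27.6-fold higher but Dcn and Col6a1 4.45-fold and 3.13-fold higher. RNA from endothelial cells was not tested as a source, with 12 of 14 markers above 0 but Kdr and Tek at log2 ratios of -0.75 and -0.18, and expression of matrix genes by the epithelial cells of the tumour-bearing group stays open, also untested.

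Acute-phase genes were higher in the tumour-bearing library. Neutrophil RNA was argued against as the source of Lcn2, since S100a8 and S100a9 together differed by -1.92 RPKM where Lcn2 gained 3998 RPKM, and liver RNA as the source of Orm1, since Alb and Apoa1 together were at 1.00 RPKM beside 62.4 RPKM of Orm1. Each check covers 1 gene and 1 source. RNA from fibroblasts, whose markers were also higher, was not tested as a source of the acute-phase genes. Fkbp5 and Zbtb16, both glucocorticoid-induced, were at 36.9 and 28.5 RPKM from 0.724 and 2.68 RPKM, and 19 other tested glucocorticoid-induced genes had a median of 0.88 (interval 0.07 to 1.41), above the central 95% of random lists, so exposure to glucocorticoid may contribute. Of the 19 genes 15 were above 0, while Nfkbia, Cdkn1c, Sgk1 and Errfi1 went against it at log2 ratios of -1.48, -0.63, -0.10 and -0.08, and the median was 0.94 over 17 genes without Ddit4 and Nfkbia, seen before that list was drawn up. Corticosterone was not measured, 2 of the 20 genes are in another list, and inflammation in the tumour-bearing group stays open as an untested explanation.

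Immediate early genes were lower in the tumour-bearing library, with a median of -0.95 over 19 genes. After the trend on transcript length and GC content was removed in 100 classes, the median was -1.02 (interval -1.63 to -0.55), which argues against those trends as the cause. Dissociation and sorting induce immediate early genes, and a shared difference in handling that also moves heat shock genes cannot be told apart from the groups. The heat shock median of -0.27 (interval -0.88 to -0.03) lay between the values set for and against it, with 11 of 13 genes below 0. The inducible Hspa1a and Hspa1b, near-identical copies, had log2 ratios of -0.04 and -0.04. A response of the cells to the tumour stays open and was not tested, since handling and group are the same split of 2 libraries.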
